A study of Mus musculus with 6 samples.

How the data were processed

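Liver RNA was measured on Affymetrix MG 430 2.0 arrays, 1 array per mouse, in 3 mice carrying a Retnla transgene (Tg 5, Tg 6 and Tg 7) and 3 mice without it (non-Tg 1, non-Tg 2 and non-Tg 3). Per the labels, the mice were male C57BL6/J animals aged 3 months that had eaten a high-fat diet of 21% fat and 0.15% cholesterol for 4 weeks, starting at 8 weeks of age. The labels describe each array as an individual sample, so the mouse is the replicate. Biotinylated cRNA was made from 5 µg of total RNA, per the labels' protocols.

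The deposited table holds 1 log2 signal per probe set and array for 45101 probe sets. The submitters' processing notes name GCOS, the Affymetrix array software; its version, the summary algorithm and the scaling target are not given in the sources used here. The values themselves show the scale: they run from -2.64 to 16.8, which is a log2 range, and the mean of the antilogged signals with 2% trimmed at each end is 500.0 on each of the 6 arrays, so the arrays were scaled to a common target before deposit. The quantiles differ between arrays, so the authors' log2 values were not quantile normalized. Median log2 signals ran from 6.49 to 6.74. No 2 arrays shared a value for any probe set at the printed precision, and Pearson correlations between arrays across probe sets ran from 0.881 to 0.891. No scanner files and no detection calls were used, and the number of arrays limits the precision.

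The 64 Affymetrix control probe sets were set aside, which left 45037. GEO's platform annotation gave 1 gene symbol for 34945 of these, several for 932 and none for 9160. Of the 34945, 34741 were matched by Entrez number to a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. No genome build is named for these data, so that table served only for names and for which genes lie next to each other. Probe sets with several symbols or none took no part in the gene tests.

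Signals were kept as deposited, with nothing added before the log, because the table was already on the log2 scale. Probe sets were kept when their mean over the 6 arrays lay above the 40th percentile, a log2 signal of 5.63, which left 27022 probe sets. For each gene the probe set with the highest mean stood for the gene, giving 12705 genes, and 5765 of these genes had several kept probe sets. Tg and non-Tg livers were compared with limma 3.58.1 (R 4.3.3, statmod 1.5.0), using lmFit and eBayes with an intensity trend, 2-sided, and p-values were adjusted by Benjamini and Hochberg over the 12705 genes at a threshold of 0.05. Each SE is the moderated one of that fit, with 4 residual degrees of freedom and 9.61 after moderation. For single genes an exact permutation test over the 20 assignments of mice to groups was also run; with 3 mice against 3 it cannot give a p below 0.1. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

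Before the data were examined, 44 gene lists were written down, covering bile acid, cholesterol and fatty acid metabolism, nuclear receptor targets, stress and inflammation, circadian and sex-biased genes, liver zones, and markers of other cell types or tissues that a piece of liver can hold. They name 1014 genes, of which 789 had a value. One of the lists, 22 genes of cholesterol and bile acid metabolism, was read gene by gene and not tested as a list, although 19 of its genes had a value. The 42 other lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 42 lists. Members were also counted by their p over all genes and adjusted over the list alone. Camera with an estimated correlation, and fry, served as alternatives.

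The genes named in the text follow a rule set before the data were examined. It takes the members of the Resistin-like family, 22 genes of cholesterol and bile acid metabolism chosen in advance, and the genes past the threshold with no overlap between groups. Because fewer than 5 genes passed in either direction, each direction was filled to 8 genes with those of smallest p that differed at least 1.5-fold without overlap, and these are said not to pass; gene models without an assigned name were passed over. From each list it takes members that passed adjusted over the list alone, at most 4, and the first members by p of a list called by camera. Of the 22 genes, 19 had a value; the other 3 were not analysed here.

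The arrays fell into 2 sets by the bioC control, a bacterial transcript spiked in before hybridization. This was seen only after the data were examined, and the sets were then used as a block in an added fit. Further alternatives were other constants added before the log, other filters on dim probe sets, quantile normalization, centring on the median, moderation without the trend or with robust variance, array weights, other ways to combine probe sets, other thresholds, a Student test per gene, and leaving out each mouse in turn. The procedure was tested on simulated data in 20 runs of 12705 genes with 200 genes changed at once, spread evenly over the sizes given next. It recovered 12.5% of the genes changed by 1.5-fold, 38.5% at 2-fold, 69.8% at 4-fold and 87.0% at 16-fold, with 3.94% false calls. With a block the shares were 4.1%, 25.2%, 60.3% and 81.2%. The simulated arrays held no difference between the bioC sets, so these lower shares do not show what the block costs or gains in the real data.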

Results

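Gene expression was measured in the livers of 6 male mice fed a high-fat diet, 3 carrying a transgene for Retnla and 3 without it. Retnla encodes resistin-like molecule alpha, a secreted protein of the resistin family best known from alternatively activated macrophages. Each mouse gave 1 array, and 12705 genes were tested. The comparison asks which liver genes differ with the transgene under a diet rich in fat and cholesterol.

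Retnla itself was by far the most different gene. Its log2 signal was 15.996 ± 0.073 (SD, n = 3) in Tg livers and 6.64 ± 0.71 (SD, n = 3) in non-Tg livers, a log2 difference of 9.36 ± 0.28 (SE; limma adjusted p = 4.07e-07). The non-Tg signals lay near the median of all probe sets on the arrays, 6.49 to 6.74, and no detection calls were at hand, so the size depends on the background: with 64 added to the signals before the log, Retnla differed by 8.62. The Retnla difference was 9.94 and 9.09 within the 2 sets of arrays described below, and 9.52 with those sets as a block. The exact permutation p for Retnla was 0.1, the smallest that 3 mice against 3 can give. Among other family members, Retn was at 6.10 in Tg and 4.96 in non-Tg livers and Retnlb at 3.01 and 2.46. Both lay below the filter in the mean of the 6 arrays and took no part in the gene test; over all probe sets their limma adjusted p was 0.909 and 0.958. Retnlg was not analysed here.

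A second gene passed the threshold, and it rose in Tg livers too. Nnt encodes nicotinamide nucleotide transhydrogenase, a protein of the inner mitochondrial membrane that makes NADPH. Its log2 signal was 12.81 ± 0.18 (SD, n = 3) in Tg and 11.37 ± 0.07 (SD, n = 3) in non-Tg livers, a rise of 1.43 ± 0.12 (SE), or 2.70-fold (95% confidence interval 2.26 to 3.23; limma adjusted p = 0.00197). All 3 Tg values lay above all 3 non-Tg values. A second Nnt probe set differed by 1.13 ± 0.15 (SE). Nnt differed by 1.55 and 1.29 within the 2 sets of arrays and by 1.42 with them as a block (limma adjusted p = 0.00658). Without the intensity trend in limma's moderation the size stayed at 1.43, but the adjusted p became 0.239; over 19 limma alternatives it ran from 0.000963 to 0.239. In all, 2 of 12705 genes rose and 0 fell. At an unadjusted p under 0.05 the limma test counted 769 genes, 372 higher and 397 lower in Tg livers, where chance alone gives 635.25 on average. Over the other splits of the mice into 3 and 3 that count ran from 228 to 1686. Of the 10 splits, 2, the real one among them, gave at least 769, so this count does not set the real split apart. The groups did not overlap for 1484 genes, 11.7% against the 10% that chance gives on average.

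**Figure D1:**
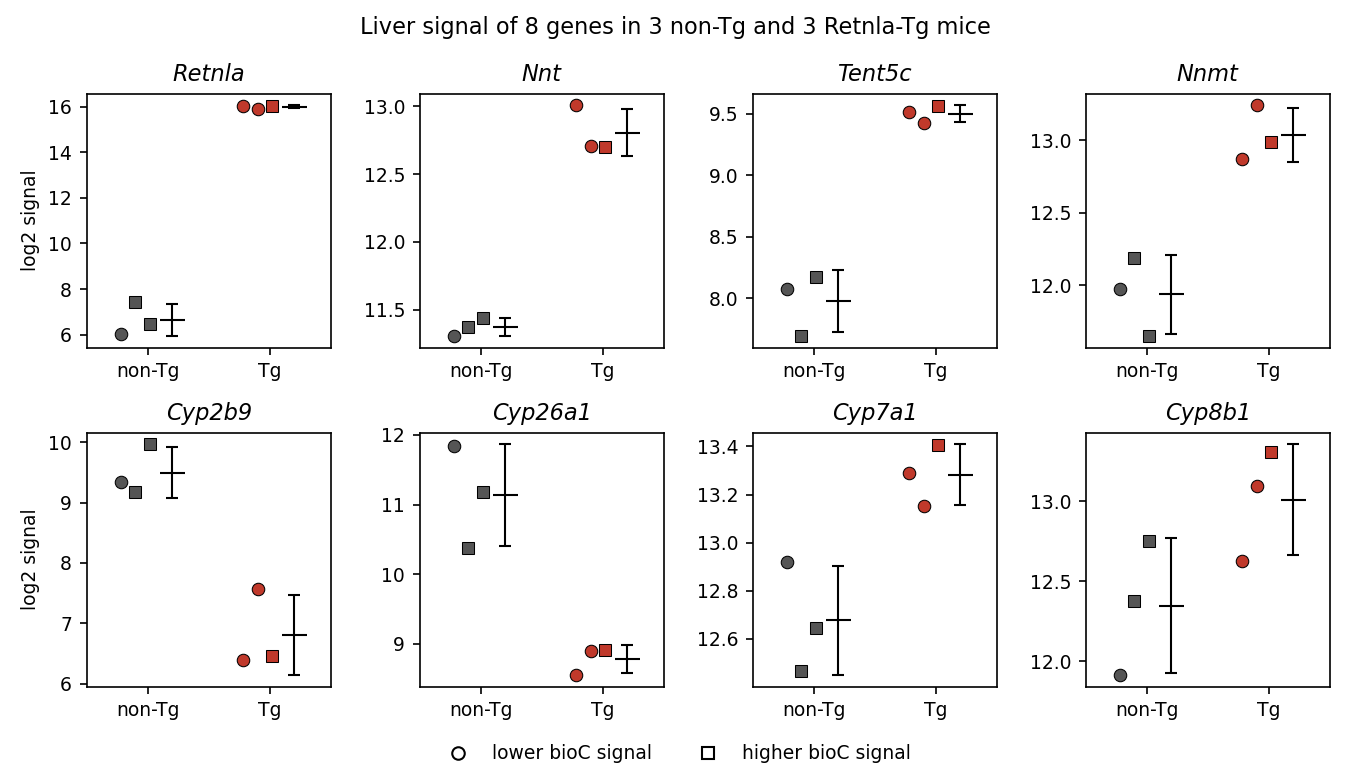
Log2 signal (vertical axis, a separate scale for each gene) of 8 genes in non-Tg and Retnla-Tg (Tg) livers. Each point is 1 mouse, circles and squares mark the arrays of lower and higher bioC signal, and the bars beside them give the mean ± SD of 3 mice; the groups do not overlap for any of these genes except Cyp8b1.

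Several further genes showed large differences without overlap that did not pass. On the higher side in Tg livers stood Tent5c, a poly(A) polymerase, with a log2 difference of 1.52 ± 0.19 (SE; limma adjusted p = 0.0579), and Nnmt, which methylates nicotinamide, with 1.10 ± 0.15 (SE; limma adjusted p = 0.0696). Selenbp1, a selenium-binding methanethiol oxidase, differed by 0.79 (limma adjusted p = 0.123), Top3b, a topoisomerase, by 1.02, Ugt2b38, a glucuronosyltransferase, by 1.14, Gstm3, a glutathione transferase, by 1.61, and Safb2 by 0.70, with limma adjusted p from 0.205 to 0.378 for these last 4. Lower in Tg livers were Cyp2b9, a steroid and drug hydroxylase, at 6.81 ± 0.67 against 9.49 ± 0.42 (SD, n = 3 each), a log2 difference of -2.69 ± 0.35 (SE), and Cyp26a1, which breaks down retinoic acid, at 8.78 ± 0.20 against 11.13 ± 0.74 (SD, n = 3 each), a difference of -2.35 ± 0.31 (SE). Both had a limma adjusted p of 0.0610. Tent5c, Nnmt, Cyp2b9 and Cyp26a1 pass when 64 is added to the signals before the log. The remaining genes on the lower side were Cnmd (-0.80), Wdfy1 (-0.92), Slc16a7, a monocarboxylate transporter (-0.62), Gas1 (-0.84), Pctp, a phosphatidylcholine transfer protein (-0.65), and Dnase2a, a lysosomal DNase (-0.97), with limma adjusted p from 0.378 to 0.653.

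Probe sets of some of these genes disagreed. For Top3b the other kept probe sets gave -0.50 and -0.44. For Safb2 they gave 0.15 and -0.01, for Pctp -0.15, for Wdfy1 -0.95, -0.21 and -0.04. Gstm3, Selenbp1, Gas1 and Tent5c had further probe sets in the same direction, at 1.36, 0.40, -0.48 and 2.44. Gstm3, Cyp2b9 and Ugt2b38 belong to families of near-identical genes whose transcripts one probe set can share.

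Of the 19 genes of bile acid and cholesterol handling chosen in advance, none passed over all genes. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 13.28 ± 0.13 in Tg and 12.68 ± 0.23 in non-Tg livers (SD, n = 3 each), with all 3 Tg values above all 3 non-Tg values. The log2 difference was 0.61 ± 0.13 (SE), or 1.52-fold (95% confidence interval 1.25 to 1.86), with a limma p of 0.000841 and an adjusted p of 0.432. Within the 2 sets of arrays Cyp7a1 differed by 0.30 and 0.85, and its second probe set gave 0.62 ± 0.17 (SE). Cyp8b1, which makes the precursor of cholic acid, differed by 0.66 ± 0.22 (SE; limma adjusted p = 0.779), and its groups overlapped. Within the 2 sets of arrays Cyp8b1 differed by 0.95 and 0.74. These compare non-Tg 1 with Tg 5 and Tg 6, and Tg 7 with non-Tg 2 and non-Tg 3. The groups did not overlap inside either set, which chance alone makes likely with a single mouse on one side. With the sets as a block Cyp8b1 differed by 0.84 ± 0.15 (SE; limma adjusted p = 0.328), which does not pass. Nr5a2, the nuclear receptor LRH-1 that binds the Cyp7a1 promoter, differed by -0.55 ± 0.15 (SE; limma adjusted p = 0.735) on the probe set with the highest mean, while other kept Nr5a2 probe sets gave 0.03 and -0.02. Differences of Srebf1 (-0.41), Nr1h3, the receptor LXR alpha (0.30), Apob (-0.20), Abcg5 (-0.37) and Abcg8 (-0.35) did not pass either. With the block these genes stood, in the same order, at -0.37, 0.31, -0.16, -0.49 and -0.59, and none passed. The other 11 of these genes, Cyp27a1 (0.00), Cyp7b1 (0.08), Nr1h4, the bile acid receptor FXR (-0.01), Nr0b2, its target SHP (-0.13), Abcb11, the bile salt export pump (-0.00), Abca1 (-0.17), Scarb1 (0.11), Srebf2 (0.13), Apoa1 (0.03), Fasn (0.03) and Scd1 (-0.11), lay between -0.17 and 0.13 on the probe set with the highest mean. Other kept probe sets gave 0.40 for Srebf2, 0.19 for Cyp7b1, -0.17 and -0.08 for Scarb1, and 0.02 and -0.01 for Abca1. For Apob the other kept probe set gave -0.00. With 3 mice per group, simulated 2-fold changes were recovered in 38.5% of cases, and in 25.2% with a block. The simulation held no difference between the sets of arrays, so it does not show how the block changes recovery in these data. In those runs 200 genes changed at once, while 2 genes passed here. The adjusted threshold is stricter when fewer genes pass, so recovery in these data may be lower. A gene that did not pass is thus not shown to be unchanged.

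Bile acid synthesis genes as a list were not called (limma camera adjusted p = 0.634), which does not show the list to be unchanged. The median log2 difference was -0.04 and the mean 0.00 over 20 measured members, 8 higher and 12 lower. Adjusted over the list alone 1 member, Cyp7a1, passed, and 0 did over all genes. Cholesterol synthesis and SREBP2 targets had a median of -0.00 and a mean of 0.04 over 20 genes (limma camera adjusted p = 0.814), lipogenesis -0.06 over 27 (0.558), and lipoproteins and their remodelling 0.02 over 28 (0.633). In the last list Lipg, endothelial lipase, passed adjusted over the list alone with a log2 difference of 1.71 ± 0.34 (SE).

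Fatty acid oxidation and drug metabolism genes leaned lower in Tg livers. Of 34 measured PPARA targets and fatty acid oxidation genes 25 were lower, with a median of -0.13 (limma camera adjusted p = 0.000151, but 0.477 with an estimated correlation). Adjusted over the list alone, 2 members passed, the fatty acid hydroxylase Cyp4a14 at -2.11 ± 0.50 (SE) and the pantetheinase Vnn1 at -1.34 ± 0.32 (SE), and Ehhadh stood at -0.41. Among 22 xenobiotic CAR and PXR targets 18 were lower, with a median of -0.19 (limma camera adjusted p = 0.00281, but 0.566 with an estimated correlation). Over 19 alternatives that p ran from 5.38e-06 to 0.307, the highest without Tg 5, where the median was -0.07. Adjusted over the list alone Cyp2b9 passed on the lower and Gstm3 on the higher side, and Cyp2c50 stood at -0.38. Genes known to be higher in female than in male liver had a median of -0.24 over 19 members, 11 of them lower (limma camera adjusted p = 0.00956, but 0.477 with an estimated correlation), with Cyp2b9, Cyp4a14 and Nt5e (-0.99) past the threshold adjusted over the list alone. Alternatives gave adjusted p from 0.000400 to 0.0904, the highest without Tg 7, where the median was -0.06. The PPARA list also differed between the sets of arrays, by a median of 0.17. Within the lower and higher sets the medians were -0.15 and -0.10 for PPARA targets, -0.17 and -0.04 for xenobiotic targets, and 0.00 and -0.41 for female-biased genes.

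Other lists called lower were the proteasome, 27 of 31 subunits lower, with a median of -0.14 (limma camera adjusted p = 2.47e-06; for instance Psmd2 at -0.30, Psma1 at -0.36 and Psmd14 at -0.35), and the mitochondrial respiratory chain, 30 of 38 lower, with a median of -0.06 (0.00956; Ndufa2 at -0.28, Uqcrc2 at -0.28 and Atp5g1 at 0.18). With an estimated correlation the camera adjusted p was 0.477 for the proteasome and 0.756 for the respiratory chain. Both lists differed between the sets of arrays, by medians of 0.14 and 0.09, and with the sets as a block the respiratory chain lost its call (limma camera adjusted p = 0.0766; 0.000214 to 0.196 over 19 alternatives), as it did without non-Tg 2 (median -0.05) or Tg 6 (-0.02). Bile acid and biliary lipid transport had a median of -0.11 over 18 genes, 15 lower (limma camera adjusted p = 0.00956, but 0.477 with an estimated correlation and 0.00172 to 0.0689 over 19 alternatives, the highest without non-Tg 1 at a median of -0.11), with Pctp past the threshold adjusted over the list alone and Abcc3 and Atp8b1 at -0.42 and -0.51. LXR targets had a median of -0.17 over 17 genes, 13 lower (0.0434, but 0.477 with an estimated correlation), although the member that passed adjusted over the list alone, Cyp7a1, was higher, and Srebf1 and Nr1h3 stood at -0.41 and 0.30. The LXR call ended in 10 of 19 alternatives (0.0107 to 0.366), among them those without non-Tg 1 (median -0.21), non-Tg 2 (-0.13), non-Tg 3 (-0.09) or Tg 7 (-0.08). Stellate cell and fibrosis genes had a median of -0.25 over 25 genes, 17 lower (0.0278, but 0.595 with an estimated correlation), with Lrat, which stores retinol as esters, at -0.93, Reln at -0.52 and Rgs5 at 0.81. That call ended without non-Tg 2 (median -0.09) or Tg 7 (-0.15) and with a filter at the 70th percentile (-0.22), and the adjusted p ran from 0.00410 to 0.551. Medians within the lower and higher sets of arrays were -0.16 and -0.06 for the proteasome, -0.07 and -0.01 for the respiratory chain, -0.13 and -0.26 for biliary transport, 0.03 and -0.32 for LXR targets, and 0.01 and -0.28 for stellate genes. In none of these 5 lists did a member pass over all genes.

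Acute phase, erythroid and T and NK cell genes leaned higher in Tg livers. Of 29 acute phase genes 23 were higher, with a median of 0.27 (limma camera adjusted p = 0.000213, but 0.566 with an estimated correlation). Over 19 alternatives that p ran from 8.96e-07 to 0.580, the highest without Tg 6, where the median was 0.06. The metal- and stress-induced metallothioneins Mt1, at 2.16 ± 0.52 (SE), and Mt2, at 2.21 ± 0.53 (SE), passed adjusted over the list alone, and Orm1 stood at 0.35. Erythroid genes had a median of 0.36 over 8 genes, 7 higher (limma camera adjusted p = 0.00956, but 0.477 with an estimated correlation and 0.00259 to 0.0774 over 19 alternatives, the highest without Tg 5 at a median of 0.20), with Hbb-b2 (0.79) and Alas2 (0.46) past the threshold adjusted over the list alone and Tfrc at 0.43. T and NK cell markers had a median of 0.53 over 11 genes, 8 higher (0.0178, but 0.638 with an estimated correlation), with Zap70 at 0.47 and the dim genes Gzma and Nkg7 at 1.39 and 2.31, or 0.82 and 0.81 with 64 added before the log. Gzma is also 1 of the 20 measured genes nearest to Nnt, described below, so its difference need not reflect immune cells. B cell markers, with a median of 0.12 over 11 genes (0.698), and neutrophil markers, with 0.12 over 10 (0.907), were not called, and with the sets of arrays as a block their medians were -0.01 and -0.02. The acute phase and T and NK lists also differed between the sets of arrays, by -0.30 and -0.83. With the sets as a block the T and NK list had a median of 0.47 and lost its call (limma camera adjusted p = 0.128; 0.00282 to 0.152 over 18 alternatives), as it did without non-Tg 2 (0.41), Tg 5 (0.68) or Tg 6 (0.50), while the acute phase list had a median of 0.14 and kept it (0.00112, but 0.562 with the block and an estimated correlation). Within the lower and higher sets the medians were 0.20 and -0.01 for acute phase genes, 0.47 and 0.25 for erythroid genes, and 0.52 and 0.50 for T and NK markers.

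Cell cycle genes had a median of 0.32 over 26 genes, 17 higher (limma camera adjusted p = 0.0197, but 0.477 with an estimated correlation). That call ended without non-Tg 1 (median 0.27) or Tg 6 (0.26), and over 18 alternatives the adjusted p ran from 0.00904 to 0.127. The member that passed adjusted over the list alone was Cdkn1a, which encodes the cell cycle inhibitor p21, at 8.80 ± 1.54 in Tg and 5.10 ± 0.90 in non-Tg livers (SD, n = 3 each), a difference of 3.70, or 2.39 with 64 added before the log, while the cyclin-dependent kinase Cdk1 stood at 0.85 and the cyclin Ccne1 at 0.91. Periportal hepatocyte genes were called higher (0.0197, but 0.595 with an estimated correlation) on a median of 0.02 and a mean of 0.14 over 19 genes, with Etnppl (0.42) and the urea cycle enzyme Asl (0.45) past the threshold adjusted over the list alone and Pck1 at 0.49. The periportal call ended in 5 of 19 alternatives (0.00306 to 0.292), among them those without non-Tg 1 (median 0.01) or Tg 5 (0.03). Type 2 and alternative macrophage activation, a list that contains Retnla, had a median of 0.21 over 14 genes (limma camera adjusted p = 0.00956, but 0.477 with an estimated correlation), and lost its call without non-Tg 1 (median 0.15) or Tg 6 (0.23), with adjusted p from 0.00330 to 0.139 over 19 alternatives. Without Retnla its other 13 members had a median of 0.19 and an unadjusted limma camera p of 0.108, with the macrophage receptor Mrc1 at 0.23 and Arg1 at 0.09. Within the lower and higher sets of arrays the medians were 0.33 and 0.14 for the cell cycle, 0.15 and 0.05 for periportal genes, and 0.27 and 0.04 for the type 2 list.

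**Figure D2:**
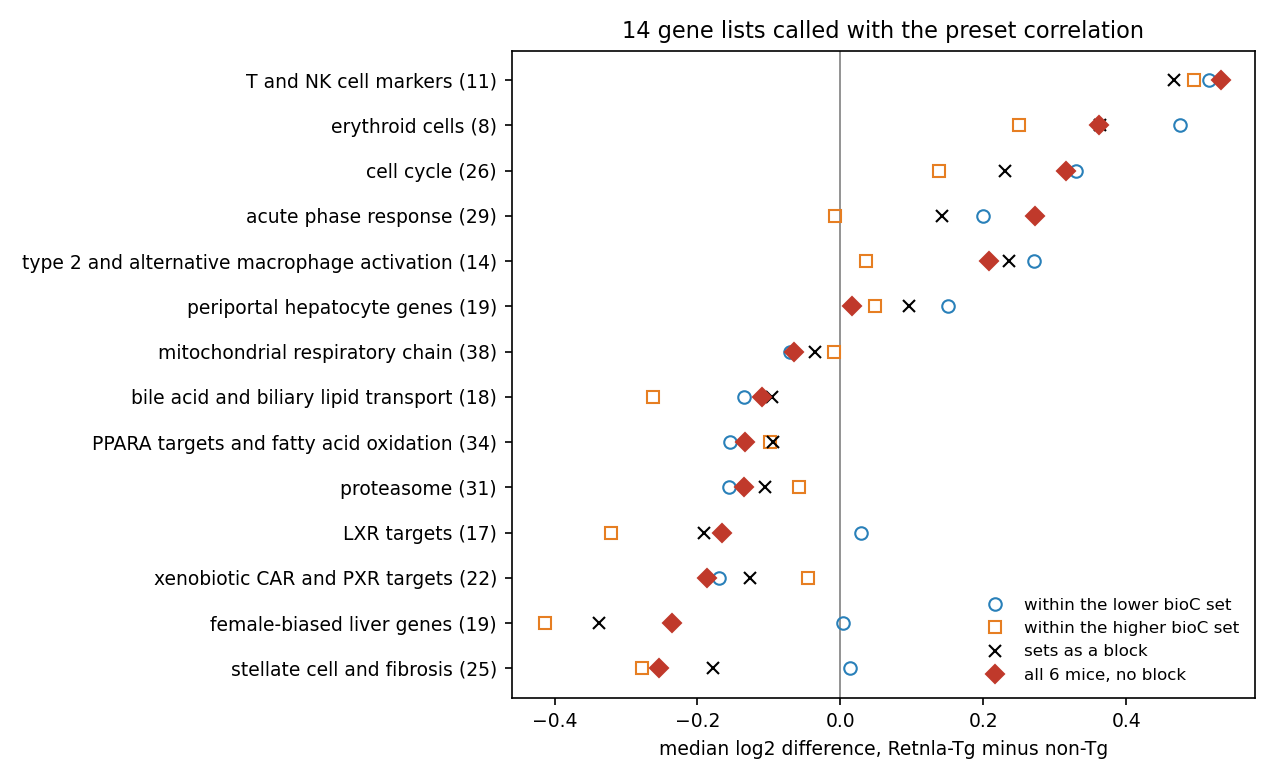
Median log2 difference, Retnla-Tg minus non-Tg (horizontal axis), of the 14 gene lists called by camera with the preset correlation, with the number of measured genes in parentheses. Diamonds use all 6 mice, crosses add the bioC sets of arrays as a block, and open circles and squares are medians within the lower and higher sets; LXR targets run from -0.32 to 0.03 between the sets.

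Kupffer cell, cholangiocyte and liver endothelial markers were not called without a block. Kupffer cell and macrophage markers had a median of 0.27 over 26 genes, 23 higher (limma camera adjusted p = 0.0612, and 0.622 with the sets of arrays as a block); within the lower and higher sets their median was 0.57 and -0.47. Cholangiocyte markers had a median of -0.24 over 12 genes (0.0612; 0.0115 with the block, and 0.548 with the block and an estimated correlation) and liver endothelial markers a median of 0.03 and a mean of -0.01 over 23 (0.814). Male-biased genes had a median of 0.06 over 19 genes, 11 higher (limma camera adjusted p = 0.0786), and passed under 7 of 19 alternatives (0.00921 to 0.365), among them the block (0.0305, but 0.548 with an estimated correlation added). Genes of the growth hormone and IGF axis had a median of -0.15 over 16 (0.179, 0.00381 with the block, and 0.548 with an estimated correlation added). The 28 lists not called had medians from -0.24 to 0.27. In these, immediate early genes had Btg2 (1.14), Zfp36 (0.87) and Dusp1 (0.99) on the higher and Gadd45a (-1.33) on the lower side past the threshold adjusted over the list alone. The complement gene C6 (0.55), the tyrosine aminotransferase gene Tat (1.12), the co-chaperone gene Bag3 (0.58), the clock genes Nr1d2 (-0.40) and Bhlhe40 (-0.63), the trypsin gene Prss2 (2.19 on a dim probe set, 1.10 with 64 added before the log) and the fatty acid binding protein gene Fabp2 (-0.35) also passed adjusted over their lists alone, and 0 of them did over all genes.

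**Figure D3:**
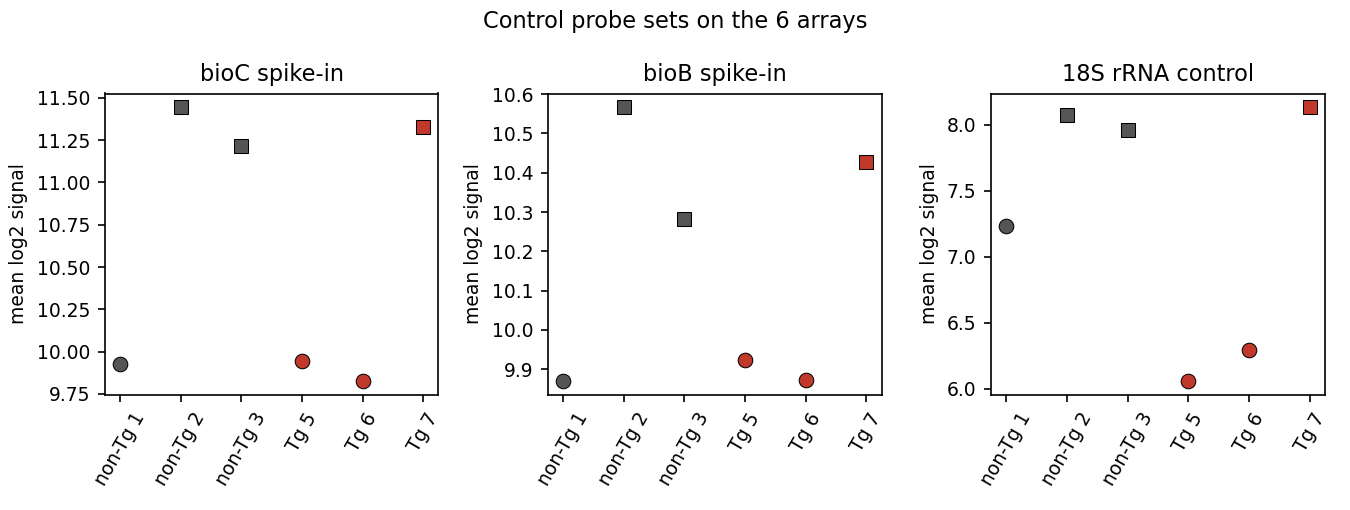
Mean log2 signal (vertical axes, a separate scale for each panel) of the bioC and bioB spike-in controls and the 18S rRNA control on each of the 6 arrays. Red points are Tg and grey points non-Tg mice; squares mark the 3 arrays with bioC from 11.2 to 11.4 and circles the 3 with bioC from 9.83 to 9.94.

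The 6 arrays fell into 2 sets that cut across the groups. The bioC control was at 9.90 ± 0.06 on the arrays of non-Tg 1, Tg 5 and Tg 6 and at 11.33 ± 0.12 (SD, n = 3 each) on those of non-Tg 2, non-Tg 3 and Tg 7, and bioB and the 18S rRNA control were also higher in the latter set, by 0.54 and 1.53. The 18S control was also lower in Tg than in non-Tg livers, by a log2 difference of -0.93, which was -1.05 within the lower and 0.11 within the higher set. The 3' minus 5' signal was higher in the latter set by 0.38 for actin, 0.02 for Gapdh and 0.83 for pyruvate carboxylase. For pyruvate carboxylase it was also lower in Tg than in non-Tg livers, 2.79 ± 0.36 against 3.46 ± 0.44 (SD, n = 3 each; exact permutation p = 0.2), by -0.37 and -0.50 within the lower and higher sets, while actin differed by 0.04 and -0.08 and Gapdh by 0.07 and -0.03 there. Compared with each other, the sets differed in 19 genes, 2 up and 17 down in the higher set (limma), and in 12 lists. With the sets as a block, 4 genes passed between Tg and non-Tg livers: Retnla, Nnt, Mt1 with a log2 difference of 1.62 ± 0.18 (SE) and Onecut1, a hepatocyte transcription factor chosen here after its values were seen, with -1.35 ± 0.15 (SE; limma adjusted p = 0.0446 for both). Of the 14 called lists, 12 kept their call with the block and 0 with an estimated correlation or with fry.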

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

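The added constant of 16 and the block by bioC set were chosen after the data were examined; the other alternatives were planned. Retnla kept its direction and its call under each of 19 limma alternatives, with log2 differences from 8.62 to 9.74. Nnt kept its call under 18 of these 19, with differences from 1.28 to 1.49, and lost it without the intensity trend. Without the trend Retnla and Neto1 were called. The count of genes became 6 with 64 added before the log, 4 with 16 added, 5 with median centring, 4 with robust moderation and 4 with the bioC sets as a block. It was 6 at an adjusted p under 0.10 and 334 at an unadjusted p under 0.05 with a 1.5-fold change. The Student test per gene called 0 genes after adjustment, so both lost their call there (adjusted p = 0.161 for Retnla and 0.333 for Nnt), and 731 at an unadjusted p under 0.05. The cause was not tested; the looser thresholds admit more genes by construction.

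Of the fixed lists, 0 were called with an estimated correlation and 0 with fry, against 14 with the preset correlation, and without 1 mouse the count ran from 9 (without non-Tg 1) to 16. Leaving out a single mouse ended the call of 12 of the 14 lists, with these limma camera adjusted p (median log2 difference in parentheses). Without non-Tg 1 it was 0.0717 (0.15) for type 2 activation, 0.0689 (-0.11) for biliary transport, 0.214 (0.01) for periportal genes, 0.127 (0.27) for the cell cycle and 0.0717 (-0.21) for LXR targets. Without non-Tg 2 it was 0.0851 (-0.05) for the respiratory chain, 0.152 (0.41) for T and NK, 0.551 (-0.09) for stellate and 0.0814 (-0.13) for LXR, and without non-Tg 3 it was 0.0811 (-0.09) for LXR. Without Tg 5 it was 0.307 (-0.07) for xenobiotic targets, 0.0774 for erythroid (0.20) and for T and NK (0.68), and 0.292 (0.03) for periportal genes. Without Tg 6 it was 0.580 (0.06, against 0.27 with all mice) for the acute phase, 0.196 (-0.02) for the respiratory chain, 0.139 (0.23) for type 2, 0.128 (0.50) for T and NK and 0.0962 (0.26) for the cell cycle. Without Tg 7 it was 0.0904 (-0.06, against -0.24 with all mice) for female-biased genes, 0.0988 (-0.15) for stellate and 0.365 (-0.08) for LXR. The male-biased list, not called, passed under 7 of 19 alternatives. The LXR list lost its call in 10 of 19 alternatives, and the proteasome and PPARA lists in 0 of 19, apart from the 2 other list tests.

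Reversals fell on values near 0 or on probe sets that disagree, and none had been called. Quantile normalization left Apoa1 at 0 within rounding (-4.46e-15) and turned Nr1h4 (0.00411) and Abcb11 (0.0305), and median centring Cyp27a1 (-0.0257). Array weights turned the direction by camera of the cholesterol synthesis list from up to down. Its median was -0.0317 with these weights and -0.00225 without, so the median kept its sign. The mean of probe sets turned Scarb1 (-0.0472), Reln (0.18) and, by camera's direction, that list (median -0.0187). Probe sets without a shared-sequence suffix turned Safb2 (-0.00845). The block turned Scarb1 (-0.0452) and Abcb11 (0.00110). Without 1 mouse each, values ran from -0.47 to 0.0718 for Nr0b2, -0.0900 to 0.11 for Abcb11, -0.0487 to 0.10 for Fasn, -0.16 to 0.15 for Nr1h4, -0.0894 to 0.16 for Cyp27a1, -0.0213 to 0.0587 for Apoa1, -0.0537 to 0.30 for Srebf2, and, as list medians, 0.0204 to 0.0977 for cholesterol synthesis, -0.0915 to 0.0358 for lipogenesis and -0.0721 to -0.0143 for bile acid synthesis; the direction by camera turned in each of these lists. No paired analysis was possible because the groups share no replicate number (1 to 3 against 5 to 7). Probe sets with a mean log2 signal under 5.63 took no part in the test of 12705 genes; without that filter the count of genes was 2.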

Other observations

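The tests of a batch behind Nnt and the sex-biased genes, of a second Nnt probe set and of the spike-in controls were chosen after the result was seen; the other tests below were written down before theirs.

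Clock genes left open whether the 2 groups were sampled at different times of day. Arntl minus Dbp, which swings over the day in liver, differed by 0.64 on the log2 scale between Tg and non-Tg livers, while the circadian list had a median of 0.09 over 23 genes. Of these, 2 passed adjusted over the list alone, Nr1d2 (-0.40) and Bhlhe40 (-0.63). The groups did not overlap for 5 of the 23, against 11.7% of all genes. Per1 ran from 9.55 to 9.96 in Tg and from 9.06 to 9.41 in non-Tg livers, while Arntl, Dbp and Nr1d1 overlapped. Among the 22335 probe sets left out of the gene test because they were dim or carried no single gene symbol, 0 passed limma's test over all probe sets, and 11 had an unadjusted p under 0.001 where chance gives 22.3. The smallest p among them belonged to Moxd1, a monooxygenase-like gene of the male-biased list, chosen here after its values were seen: its log2 signal was 7.29 in Tg and 2.11 in non-Tg livers, higher in all 3 Tg mice (limma adjusted p = 0.279).

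Nnt was 2.70-fold higher in Tg livers. The C57BL/6J strain is known to carry a deletion within Nnt, and the labels give that strain background for all 6 mice, so a candidate explanation is that the Tg and non-Tg mice differed at this gene by breeding rather than through Retnla. The tables argue against an array batch, because the smaller of the differences within the 2 bioC sets was 1.29, and against a fault of one probe set, because the second gave 1.13. If a longer stretch of chromosome from another strain had come with Nnt, its neighbours may differ as well: the median absolute t of the 20 nearest measured genes lay at the 85.1th percentile of 12678 windows, between the bounds of 75 and 95 set beforehand, so this cannot be told apart from no such stretch. Among these 20, Tmem267 (-0.90), Hmgcs1 (-0.59) and Gzma (1.39) had an unadjusted limma p of 0.00588, 0.00713 and 0.0267. The others had 0.0798 or more, and none of the 20 passed adjusted over all genes. An effect of the transgene on Nnt stays open, as does a strain difference, since no genotype at Nnt was measured.

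Immune and acute phase lists differed between the bioC sets, by a median, higher minus lower, of -0.53 for Kupffer cell and macrophage markers, -0.83 for T and NK markers and -0.30 for the acute phase list. Between the groups, a block for the sets moved the median of the acute phase list from 0.27 to 0.14, of Kupffer cell markers from 0.27 to 0.07 and of T and NK markers from 0.53 to 0.47, so the sets account for little of the last. Of the spike-in controls not used to form the sets, bioB was higher in the higher set by 0.54, bioD by 0.43 and cre by 0.35. Each difference lay beyond the spread within the sets, which a difference in labelling or hybridization predicts. But these are spike-ins like bioC, by which the sets were formed, so their rise is not separate evidence for it. Whether such a difference moved the immune genes was not tested. Time of day stays open, with Arntl minus Dbp differing by -0.21 between the sets (95% interval from -2.77 to 2.35), and so does RNA quality, since the 3' minus 5' signal, compared after it was seen, was higher in the higher set by 0.83 for pyruvate carboxylase and 0.38 for actin, but by 0.02 for Gapdh. Since 2 of 3 Tg but 1 of 3 non-Tg mice lie in the lower set, part of the Kupffer cell and acute phase differences between the groups may come from it.

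Female-biased genes had a median of -0.24 in Tg against non-Tg livers and male-biased genes, a list that was not called (limma camera adjusted p = 0.0786, and 0.566 with an estimated correlation) but passed under 7 of 19 alternatives (0.00921 to 0.365), a median of 0.06, a difference of 0.30 that comes mostly from the female-biased list, whose median was -0.06 without Tg 7. An even shift between the bioC sets is argued against, because with the sets as a block the difference was 0.44, although within the lower set the female-biased median was 0.00. A female among the non-Tg mice is argued against too. No Xist or Y-linked probe set kept by the filter lay over 3.56-fold from the Tg median. Without targets of the xenobiotic receptors the female-biased median was -0.17 over 17 genes. That test cannot decide whether those targets carry the difference. Only 2 measured members are shared, and with 11 of 19 members lower the median had to stay below 0 without them. The PPARA list shares 2 members with the female-biased list as well, which was not tested. Chance stays open, as 2 of the 10 splits of the mice, the real one among them, gave a difference as large, the highest of the others 0.34. A growth hormone effect stays open as well: the growth hormone and IGF axis list had a median of -0.15 (limma camera adjusted p = 0.179, 0.00381 with the block, and 0.548 with the block and an estimated correlation).

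With 6 mice there are 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 2 genes and the highest of the others 19, with 3 splits, the real one among them, giving at least as many. For the lists, the real split called 14, and again 3 splits, the real one among them, called at least as many. The other splits called 2, 6, 8, 9, 12, 12, 12, 14 and 16 lists. The count of 14 thus does not set the real split apart. The split with 19 genes was the one between the bioC sets, which points to a structure of the samples, and with those sets as a block the real comparison gave 4 genes.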
